A study of Mus musculus with 9 samples.

How the data were processed

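RNA was sequenced from microglia, T cells and group 2 innate lymphoid cells (ILC2) taken from the brains of C57BL/6 mice aged 20 to 22 months. Every mouse had received interleukin-33 (IL-33), a cytokine released from damaged barrier and brain cells, at 400 ng per day for 7 days. The populations were sorted on surface markers, which the labels do not name. Total RNA was extracted with Trizol-LS and read as single-end reads of 75 bp. The labels describe 9 samples, 3 per population. No untreated brain is among them, so no effect of IL-33 was computed.

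Per the labels, the authors used bcl2fastq 2.20.0.422, FastQC 1.0.0, STAR 2.5.3a, Cufflinks 2.0 and DESeq2 1.1 with mouse genome build mm10. The role and order of these tools, the counting program and the strand setting are not given. The deposited table holds raw counts of reads per gene as whole numbers, although its title calls the values normalized. The scale was checked on how often each low value occurred, against a smooth curve fitted to the same library. The chi-square per degree of freedom was 0.861 to 1.10 in the 8 libraries used. Values of microglia 1 scaled by 0.8 or 1.25 and rounded gave 4.10 and 7.58. The table also has a row for reads outside genes (53.8% to 61.0% of all reads counted) and a row for ambiguous reads (0.338% to 1.23%). These 2 rows were left out, as were 27 rows whose gene symbols had been turned into dates, which held 0.0425% to 0.102% of all reads counted. Of 24423 rows, 24394 were kept, and 7851 of them had no count in any library used.

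The table has 9 library columns. One is headed ILC1, which matches no sample label, and was not used here, so that 3 microglia, 3 T cell and 2 ILC2 libraries were analysed. The labels describe 3 ILC2 samples, and whether the heading is a misspelling of ILC2 is not known. All ILC2 values therefore rest on 2 libraries. The sample titles number the samples 1 to 3 within each population, so that samples with the same number may come from the same mouse or pool, which the labels do not say. The column headings carry no replicate numbers, and the tests treat all libraries as independent. Library numbers (microglia 1 and so on) therefore follow the order of the columns and do not pair libraries across populations.

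Libraries were scaled with the TMM method of edgeR, with factors from 0.822 to 1.18. Levels are on the counts-per-million (CPM) scale of the scaled library, given as mean ± SD over libraries. Counts on genes ran from 8376609 to 13585956 per library. A gene with no count was set against a floor of 3 counts per library, which was 0.207 to 0.326 CPM. A fold against a population with no count is a lower bound computed from this floor. The log2 fold change of a fit in which a population had no count is set by the small prior count that edgeR adds. Such a value gives the direction and not the size. With 1 to 3 counts in the lower population, a ratio is given with its 95% counting interval: the mean level of the higher population over the counts of the lower one pooled over its libraries and divided by their summed scaled size. It can therefore differ from the ratio of the mean levels. In each gene given with such a ratio, leaving out 1 library moved the fold change by over 1.5 times. In part this was because no count was left in the lower population, so that the prior count set the fold. Such intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. It is not given whether reads shared by paralogs, or reads from the opposite strand, were counted, so values of close paralogs (the Klr, Ly6, Ifit and Hspa1 families) and of genes with antisense transcripts are uncertain.

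The choices of comparisons, thresholds, gene lists and genes to name were made before the data were examined. The plan was limma on log2 values, to be replaced by edgeR if the table held counts, which it did. The test was the two-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with limma 3.58.1, on 1 fit of all 8 libraries with 3 groups. It covered 13000 genes with a mean count of at least 10. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The standard error (SE) is the absolute log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.967. The 3 comparisons were ILC2 with T cells, ILC2 with microglia and T cells with microglia. A gene was highest in a population when both of its comparisons were called in that direction.

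Gene lists were tested with camera, at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over all lists of the 3 comparisons together. Lists needed 5 tested genes, which left 35 lists and set aside the erythroid list. Some genes are in several lists, so the list results are not independent of each other. Of the listed genes, 558 were matched as listed, 1 by an older symbol, and 7 (Trac, Trbc1, Trbc2, Zfp683, Ighm, Igkc and Ly6g) are not in the table. The adjusted p of a list is at the preset correlation unless the estimated one is named. The count adjusted over the list alone is given beside the count over all genes.

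Genes were named by 4 rules. The first took, per comparison, the 8 largest fold changes in each direction among called genes with no overlap between the libraries and a mean of at least 10 in the higher population, passing over predicted genes and clone names. The second took up to 4 called and 2 uncalled members of a described list. The third was a fixed set of marker genes. The fourth took the 10 genes with the largest smaller fold change per population. Some genes that these rules took are not reported here. Gene positions are from the RefSeq annotation of mm10. The pipeline was tested on simulated data with the same group sizes, with 63 to 66 genes changed at each size among 12363 to 12417 tested. By edgeR, 2-fold changes were recovered in 0% of genes in each comparison, 4-fold changes in 3.08% to 4.69% and 8-fold changes in 11.1% to 21.2%.

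The alternatives were DESeq2 1.42.0 and its size factors, no filter or a filter of 50, prior counts of 0.1 and 5, no abundance trend, only the 2 groups compared, other fold change thresholds, the estimated correlation, and each library left out in turn. Added after the data were seen were the newer quasi-likelihood method of edgeR, limma-voom, quantile normalization with limma-voom, and a fit without microglia 1 and microglia 3. That fit leaves 1 microglia library, and each fit without an ILC2 library leaves 1 ILC2 library. A call lost in such a fit may come from the fewer libraries alone. The ranges of the adjusted p of a gene over settings include only fits that leave out libraries of the populations compared.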

Results

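Transcripts were counted in microglia, the resident macrophages of the brain, in T cells, and in ILC2, lymphocytes without rearranged antigen receptors that make type 2 cytokines. The series asks how gene expression differs between these populations in the aged brain after IL-33. The 3 microglia libraries held 12047894, 11868769 and 10705652 counts on genes, the 3 T cell libraries 8376609, 13585956 and 8767738, and the 2 ILC2 libraries 10544868 and 12585870. Between 11390 and 12620 genes were detected per library. The gene with the most counts was Cst3, which encodes cystatin C, in microglia (4.16% to 4.77% of counts), Actb in T cells (2.54% to 2.93%) and Tmsb4x in ILC2 (2.23% to 3.55%). Levels below are means ± SD over 3 microglia, 3 T cell and 2 ILC2 libraries, and log2 fold changes are given ± SE. The p-values measure only the spread between these libraries, which may be technical in part.

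Marker transcripts followed the population names. Cd3e, a signalling chain of the T cell receptor, was at 1824 ± 403 CPM in T cells, 12.4 ± 14.1 in ILC2 and 0.607 ± 1.05 in microglia. Cd8a, the co-receptor of cytotoxic T cells, was at 924 ± 70.0 CPM in T cells, and Cd4, the co-receptor of helper T cells, at 209.0 ± 74.7. Tmem119, a surface protein of microglia, was at 3645 ± 569 CPM in microglia, 55.84 ± 44.97 in T cells and 19.5 ± 0.256 in ILC2. Gata3, a transcription factor of type 2 lymphocytes, was at 877.6 ± 326 CPM in ILC2, 160.5 ± 57.2 in T cells and 0.303 ± 0.441 in microglia. Rora, a transcription factor needed for ILC2 development, was at 331.8 ± 56.3 CPM in ILC2 and 143.4 ± 55.1 in T cells. Foxp3, the transcription factor of regulatory T cells, was at 57.3 ± 29.6 CPM in T cells, 21.8 ± 5.98 in microglia and 18.9 ± 12.8 in ILC2. Thy1, a surface protein of lymphocytes, was at 396.9 ± 70.7 CPM in T cells and 164.7 ± 17.7 in ILC2. Il33 itself was at 18.9 ± 13.3 CPM in ILC2, 4.91 ± 8.16 in T cells and 4.59 ± 6.99 in microglia.

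**Figure D1:**
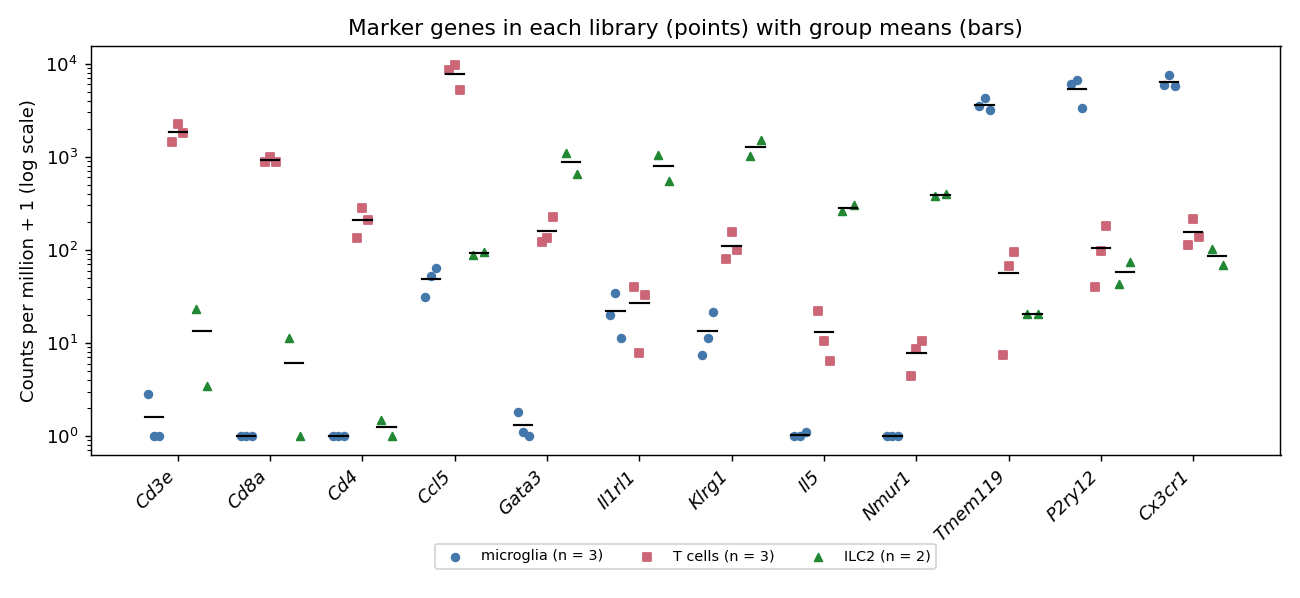
Levels of 12 marker genes in each library, as CPM plus 1 on a log scale, with points for libraries and bars for means. Cd3e was at 1824 CPM in T cells, Il5 at 284.1 CPM in ILC2 and Cx3cr1 at 6402 CPM in microglia.

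Libraries of the same population were the most alike. Pearson's r of log2 levels across genes, which are not independent replicates, was 0.756 to 0.819 in the 7 pairs of libraries within a population and 0.527 to 0.753 in the 21 pairs between populations. The first principal component held 42.3% of the variance and set microglia apart from both lymphocyte populations, and the second held 14.3% and set ILC2 apart from T cells.

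**Figure D2:**
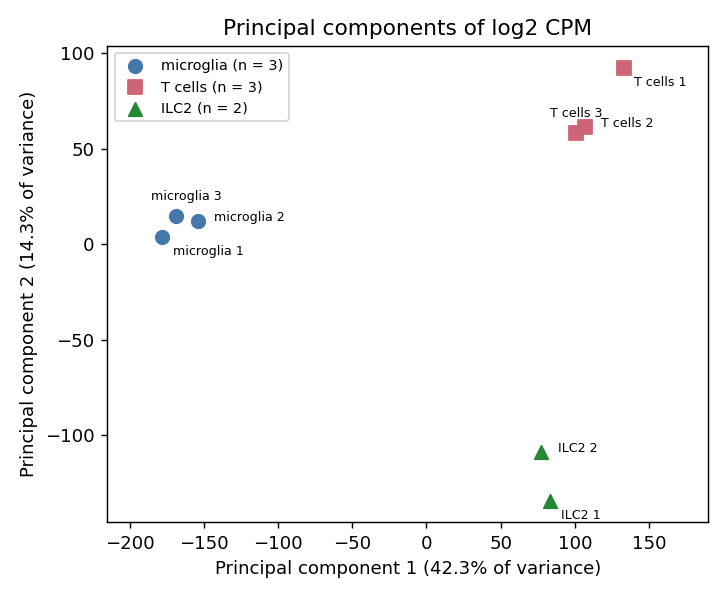
Principal components of log2 CPM for the 8 libraries, with points coloured by population. Microglia lie apart on component 1 (42.3% of the variance), and ILC2 lie apart from T cells on component 2 (14.3%).

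The comparison of ILC2 with T cells asked which transcripts separate the lymphocyte populations of the treated aged brain. Il1rl1, which encodes the IL-33 receptor, was at 799.7 ± 349 CPM in ILC2 and 25.9 ± 16.8 in T cells, a log2 fold change of 4.95 ± 0.75. Il5, the growth factor of eosinophils, was at 284.1 ± 31.6 CPM in ILC2 and 11.96 ± 7.95 in T cells, a log2 fold change of 4.57 ± 0.64. Nmur1, the receptor of the neuropeptide neuromedin U, was at 384.5 ± 12.4 CPM in ILC2 and 6.83 ± 3.13 in T cells, a log2 fold change of 5.81 ± 0.55. Cd3d, a signalling chain of the T cell receptor, was at 5.95 ± 3.81 CPM in ILC2 and 1465 ± 304 in T cells, a log2 fold change of -7.94 ± 0.68. Ccl5, a chemokine of effector lymphocytes, was at 91.1 ± 4.14 CPM in ILC2 and 7844 ± 2375 in T cells, a log2 fold change of -6.43 ± 0.50. The adjusted p was 0.0173 for Il1rl1, 0.0116 for Il5, 0.00706 for Nmur1 and 0.00142 for both Cd3d and Ccl5. In every gene named here as called, each library of one population lay above each library of the other. In build mm10, Il1rl1 lies on chromosome 1 from 40404864 to 40465418, Nmur1 on chromosome 1 from 86386242 to 86389361 and Il5 on chromosome 11 from 53720794 to 53725103. Ccl5 lies on chromosome 11 from 83525778 to 83530518 and Cd3d on chromosome 9 from 44981769 to 44987052, all annotated as protein-coding genes. Over all settings the adjusted p ran from 8.90e-11 to 0.0775 for Il1rl1 (highest without ILC2 1) and from 3.60e-09 to 0.0787 for Il5 (highest without ILC2 2). Il1rl1 also lost its call without T cells 3 (0.0542) and Il5 without ILC2 1 (0.0550). The log2 fold change became 5.23 for Il5 without T cells 1 and -8.80 for Cd3d without ILC2 1.

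In all, edgeR called 56 genes higher and 64 lower in ILC2 than in T cells, out of 13000 tested, with 1221 at an unadjusted p under 0.05. The libraries did not overlap in 25.2% of genes, where chance gives 20%. With 1 library left out, the 56 higher genes became 33 without T cells 1, 32 without ILC2 1 and 18 without ILC2 2. The 64 lower genes became 38 without T cells 1 and 35 without T cells 2. DESeq2 called 239 higher and 290 lower.

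Among the largest differences, Cd6, a co-receptor of T cells at 424.5 ± 109 CPM, had no count in ILC2, at least 1768-fold lower. Sh2d1a, an adaptor of SLAM receptors, was at least 1082-fold lower in ILC2, Slfn1, a Schlafen family gene, at least 714-fold and Samd3 at least 522-fold. Slamf7 was at least 449-fold lower and Eomes, a transcription factor of cytotoxic lymphocytes, at least 315-fold. The natural killer receptor genes Klrc1 and Klre1 had no count in ILC2 and were at 112.2 ± 71.0 and 100.9 ± 51.2 CPM in T cells, highest in T cells 2. In the other direction, Prss34, a basophil protease, was at 167.3 and 608.5 CPM in ILC2 1 and ILC2 2 and had no count in T cells, with a log2 fold change of 15.71 without ILC2 1 and 13.82 without ILC2 2. The size of both values depends on the prior count. Mcpt8, another basophil protease, was at 84.9 and 345.8 CPM in the same libraries and 0.365 ± 0.633 CPM in T cells. Mras, a small GTPase, was at least 153-fold higher in ILC2, Naprt, an enzyme of NAD synthesis, at least 81.7-fold, Nuak2, a kinase, at least 31.1-fold and Depdc7 at least 19.1-fold. Arhgef10l was at 79.31 CPM in ILC2 1 and 14.59 in ILC2 2 and had no count in T cells, with a log2 fold change of 10.33 without ILC2 1 and 12.75 without ILC2 2. These values too depend on the prior count. Cysltr1, the receptor of cysteinyl leukotrienes, was at 226.6 ± 105 CPM in ILC2 and 0.432 ± 0.748 in T cells. Some of these calls were lost on leaving out 1 library. Klrc1 lost its call without ILC2 1 (adjusted p = 0.0530), ILC2 2 (0.0595) or T cells 2 (0.0506), and Klre1 without ILC2 2 (0.0535) or T cells 2 (0.0506). Slamf7 lost it without ILC2 1 (0.122), ILC2 2 (0.128), T cells 1 (0.0620) or T cells 2 (0.0541), and Eomes without T cells 1 (0.0580) or T cells 2 (0.0511). Mcpt8 lost it without ILC2 2 (0.161) or T cells 1 (0.0665), and Arhgef10l without ILC2 1 (0.0982) or any T cell library (0.0535 to 0.0620). Depdc7 lost it without any of the 5 libraries (0.0633 to 0.0889). Fitted to only the 2 groups compared, the adjusted p was 0.252 for Nuak2 and 0.401 for Depdc7, and with the newer quasi-likelihood method it was 0.0998 and 0.330. Depdc7 was also at 0.0716 with limma-voom and 0.0679 with quantile normalization and limma-voom. Across these 8 genes the lowest adjusted p of any setting ran from 9.54e-12 for Klrc1 to 4.78e-05 for Mcpt8.

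Genes of ILC2 identity were higher in ILC2 as a group. Of 24 tested members, 4 were higher (14 when adjusted over the list alone), with an adjusted p of 2.40e-14 for the list. The basophil genes Prss34 and Mcpt8 were higher in the same ILC2 libraries, and the share of basophils in this change is not known. Both were higher in ILC2 2 than in ILC2 1. In ILC2 1 and ILC2 2, Il1rl1 was at 1046 and 553.2 CPM, Gata3 at 1108 and 647.4 and Ccr8 at 1461 and 930. Klrg1 went the other way, at 1026 and 1519 CPM. Klrg1, an inhibitory receptor of activated lymphocytes, was at 1272 ± 349 CPM in ILC2 and 110.5 ± 39.5 in T cells, a log2 fold change of 3.52 ± 0.50. Ccr8, a chemokine receptor of type 2 lymphocytes, was at 1195 ± 375 and 67.0 ± 8.18 CPM, and Cd81, a tetraspanin, at 887.6 ± 35.8 and 214.8 ± 38.3 CPM. Cd81 is not particular to ILC2, since it was at 5588 ± 991 CPM in microglia. Gata3 had a log2 fold change of 2.45 ± 0.62 and did not pass the test (adjusted p = 0.146, and 0.000135 to 0.450 over the other settings). Arg1, an enzyme that breaks down arginine, was at 2124 ± 539 CPM in ILC2 and 56.7 ± 39.6 in T cells and did not pass either (adjusted p = 0.146, and 1.56e-05 to 0.366 over the other settings). The call was lost for Klrg1 without ILC2 2 (adjusted p = 0.0664), without T cells 1 (0.0511) and without T cells 3 (0.0507), within a range of 5.32e-10 to 0.0664. Ccr8 lost its call without any 1 of the T cell or ILC2 libraries, with an adjusted p of 0.0664 (without ILC2 2) to 0.113 (without ILC2 1), from a low of 2.23e-13 over all settings.

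Type 2 cytokines and other ILC2 mediators were also higher in ILC2 as a group. Of 21 tested members, Il5 and Cxcl2, a neutrophil-attracting chemokine, were called, 9 when adjusted over the list alone (adjusted p = 3.49e-13 for the list). Cxcl2 was at 112.3 ± 55.4 CPM in ILC2 and 155.2 ± 78.3 in microglia. Basophils make type 2 cytokines too, and their genes Prss34 and Mcpt8 were higher in the same ILC2 libraries, so that the share of each cell type in this change is not known. Prss34 was at 167.3 and 608.5 CPM in ILC2 1 and ILC2 2. In the same order, Il5 was at 261.8 and 306.4 and Cxcl2 at 151.5 and 73.1. Il13 and Areg, described next, were at 27.4 and 21.3 and at 187.6 and 244.5. None of these differed between the libraries as Prss34 did, whereas Calca, given below, did. Il13, a cytokine that acts on macrophages and epithelium, was at 24.3 ± 4.33 CPM in ILC2 with 1 count in the T cell libraries, an 821-fold ratio (95% counting interval 147 to 32430), and did not pass the test (adjusted p = 0.164). Areg, the growth factor amphiregulin, was at 216.0 ± 40.2 CPM in ILC2 and 6.47 ± 5.15 in T cells, also short of the threshold (adjusted p = 0.144). Calca, the precursor of calcitonin gene-related peptide, was at 179.7 CPM in ILC2 1, 677.3 in ILC2 2 and 17.7 ± 9.68 in T cells (adjusted p = 0.104), and like Prss34 and Mcpt8 it was higher in ILC2 2 than in ILC2 1. In some other settings these 3 genes passed: the adjusted p ran from 0.00146 to 0.399 for Il13, from 5.67e-05 to 0.432 for Areg and from 4.24e-05 to 0.600 for Calca. The 18 receptors of neuropeptides and lipid mediators were higher as a list (adjusted p = 1.68e-08), and Nmur1, Cysltr1 and Ramp1 were called, 6 when adjusted over the list alone. Ramp1, a subunit of the receptor for calcitonin gene-related peptide, was at 792.0 ± 254 CPM in ILC2 and 105.8 ± 39.7 in T cells, a log2 fold change of 2.90 ± 0.39. Its adjusted p ran from 2.50e-09 to 0.0582 (without ILC2 2), and that of Cxcl2 from 1.57e-06 to 0.114 (without ILC2 1), with the call of Cxcl2 also lost without any T cell library (0.0590 to 0.0749), with limma-voom (0.0663) and with quantile normalization and limma-voom (0.0577). Of 15 genes of tissue residency and inhibitory receptors, 2 were called higher, among them Rgs1, a brake on chemokine signalling (2420 ± 406 CPM in ILC2 and 515 ± 123 in T cells), and the list did not pass (adjusted p = 0.931).

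T cell genes were lower in ILC2. Of 20 genes of the T cell receptor complex and its signalling, 5 were lower (15 when adjusted over the list alone; adjusted p = 2.60e-36). Cd4 was at 0.242 ± 0.343 CPM in ILC2, a log2 fold change of -9.70 ± 1.16, and Cd8b1, the second chain of the Cd8 co-receptor, was at 4.002 ± 0.165 CPM in ILC2 and 1943 ± 394 in T cells. Cd4 had 6 counts in ILC2 1 and no count in ILC2 2, and its log2 fold change was -14.16 without ILC2 1 and -8.72 without ILC2 2. Cd8a was at 10.34 CPM in ILC2 1 and 0 in ILC2 2, against 924 ± 70.0 in T cells. Its log2 fold change was -16.31 without ILC2 1 and -6.48 without ILC2 2. For both Cd4 and Cd8a the value without ILC2 1 rests on no count in ILC2 and is set by the prior count. Cd3e did not pass, with a log2 fold change of -7.20 ± 1.44 (-9.52 without ILC2 1 and -6.35 without ILC2 2; adjusted p = 0.0603, and 2.93e-06 to 0.251 over the other settings), nor did Cd8a (adjusted p = 0.118, 0.00489 without ILC2 1, 0.00986 without ILC2 2, and 1.02e-05 to 0.215 over the other settings). Cd3g, a further receptor chain, was at 675.0 ± 164 CPM in ILC2 and 1960 ± 284 in T cells (adjusted p = 0.118, and 2.33e-05 to 0.401). The adjusted p of Cd8b1 was 0.154 without ILC2 1 and 0.177 without ILC2 2, from a low of 3.05e-09. The 10 regulatory T cell genes did not pass as a list (adjusted p = 0.331). Of 12 genes of naive and central memory T cells, 3 were lower (8 over the list alone; adjusted p = 2.67e-15). Among them were S1pr1, the receptor for leaving tissue, with a log2 fold change of -4.01 ± 0.44, and Klf2, which drives S1pr1, with -3.60 ± 0.57. The adjusted p of Klf2 was 0.130 without ILC2 2, 0.0762 without ILC2 1, 0.0993 with limma-voom and 0.110 with quantile normalization and limma-voom, from a low of 3.69e-08.

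Cytotoxic and effector genes were lower in ILC2 as well. Of 20 members, 7 were lower, 17 when adjusted over the list alone (adjusted p = 7.05e-40, and adjusted p = 0.00905 with an estimated correlation). Fasl, the death receptor ligand, had 2 counts in the ILC2 libraries against 172.7 ± 11.5 CPM in T cells, a ratio of 2158 (95% counting interval 597 to 17820). Gzmk, a granzyme, was at 1.49 ± 2.11 CPM in ILC2 and 711.6 ± 123 in T cells, with an adjusted p of 2.93e-06 to 0.0814 over the other settings. All of its counts in ILC2 were in ILC2 1, and its log2 fold change was -15.93 without ILC2 1, where the prior count sets the size, and -7.89 without ILC2 2. Gzmk lost its call without T cells 1 (0.0814), T cells 2 (0.0797) or T cells 3 (0.0663) and without the abundance trend (0.0613). Ifng, the type 1 cytokine interferon gamma, was at 2.22 ± 3.14 and 305.1 ± 145 CPM and did not pass (adjusted p = 0.264, and 6.86e-05 to 0.604 over the other settings). Of 10 genes of natural killer cells and ILC1, 2 were lower (adjusted p = 1.14e-09, and adjusted p = 0.0482 with an estimated correlation). Of 8 ILC3 and type 17 genes, 2 were lower when adjusted over the list alone (adjusted p = 0.000287 for the list, adjusted p = 0.144 with an estimated correlation).

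Interferon response genes were lower in ILC2 than in T cells. Of 19 members, 4 were lower (8 when adjusted over the list alone; adjusted p = 1.71e-17). Ifi27l2a was at 69.0 ± 25.5 CPM in ILC2 and 870.4 ± 72.8 in T cells, a log2 fold change of -3.66 ± 0.35. Ifit3, which acts against viral RNA, had 1 count in the ILC2 libraries, a ratio of 1320 (95% counting interval 237 to 52130). Of 22 cytokine receptor genes, 4 were lower (adjusted p = 0.00224, and adjusted p = 0.0487 with an estimated correlation). Il2rb, the beta chain of the interleukin-2 receptor, had a log2 fold change of -3.02 ± 0.31, and Il21r, the receptor of interleukin-21, of -3.07 ± 0.43 (adjusted p from 1.47e-09 to 0.0788 over the settings, highest without ILC2 1). Of 19 chemokine receptor and adhesion genes, 4 were lower and 1, Ccr8, was higher (adjusted p = 0.00186, and adjusted p = 0.0487 with an estimated correlation). Of 12 mast cell, basophil and eosinophil genes, Prss34 and Mcpt8 were higher, with an adjusted p of 0.000163 for the list, and adjusted p = 0.256 with an estimated correlation. The 10 oligodendrocyte genes were higher as a list (adjusted p = 0.000136, and adjusted p = 0.0509 with an estimated correlation). The 16 growth factor genes were higher as a list (adjusted p = 0.0147, and adjusted p = 0.201 with an estimated correlation), although its called member in edgeR, Pdgfb, a subunit of platelet-derived growth factor, was lower. Pdgfb lost its call without ILC2 1 (adjusted p = 0.144), ILC2 2 (0.0889), T cells 1 (0.0703) or T cells 3 (0.0599), with limma-voom (0.0696), with the newer quasi-likelihood method (0.0777) and with only the 2 groups compared (0.0762), within a range from 3.37e-05. The 21 lists that did not pass had an adjusted p of 0.126 to 0.970. With an estimated correlation, 10 of the 14 list calls held, at an adjusted p of only 0.00905 to 0.0487.

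**Figure D3:**
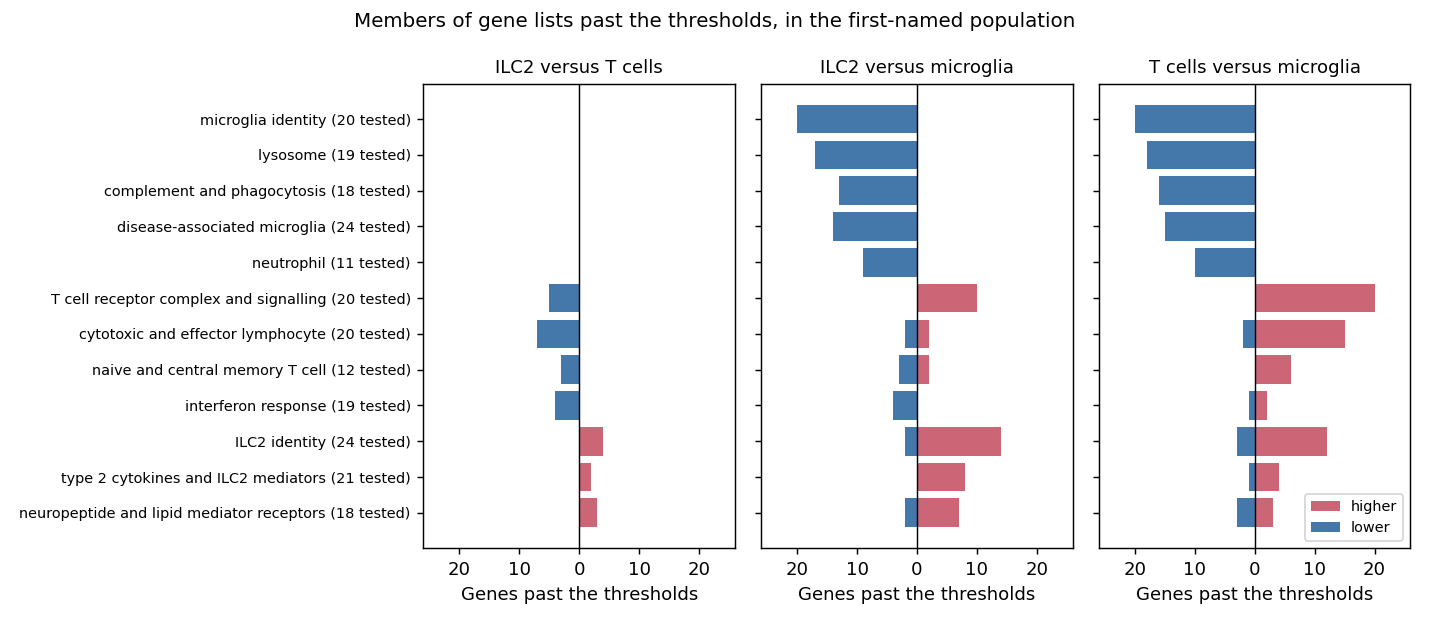
Members of 12 gene lists called higher (red) or lower (blue) in the first-named population, as numbers of genes, in the 3 comparisons. All 20 microglia identity genes were lower in ILC2 and in T cells than in microglia.

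The comparison of ILC2 with microglia asked how brain ILC2 differ from the resident macrophages. Icos, a co-stimulatory receptor of lymphocytes, was at 491.7 ± 41.0 CPM in ILC2 and had no count in microglia, at least 1617-fold higher. Klrg1 was at 1272 ± 349 CPM in ILC2 and 12.4 ± 7.29 in microglia, a log2 fold change of 6.68 ± 0.57. Il5 had 1 count in the microglia libraries, a ratio of 8410 (95% counting interval 1509 to 332200). Cx3cr1, the fractalkine receptor of microglia, was at 85.0 ± 23.2 CPM in ILC2 and 6402 ± 1007 in microglia, a log2 fold change of -6.24 ± 0.45. The adjusted p was 5.57e-05 for Icos, 0.000174 for Klrg1, 0.000162 for Il5 and 0.000107 for Cx3cr1. In build mm10, Icos lies on chromosome 1 from 60960773 to 61000322 and Cx3cr1 on chromosome 9 from 120048683 to 120068296.

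In this comparison edgeR called 649 genes higher and 619 lower in ILC2, with 3126 at an unadjusted p under 0.05. The libraries did not overlap in 43.0% of genes, where chance gives 20%. The 649 higher genes became 342 without ILC2 2. The 619 lower genes became 402 without ILC2 1, 369 without ILC2 2 and 393 without microglia 2. Neutrophil transcripts differed between the microglia libraries: S100a8, a calcium-binding protein of neutrophils, was at 26452 CPM in microglia 1, 4072 in microglia 2 and 33382 in microglia 3. A fit without microglia 1 and microglia 3 leaves 1 microglia library, so the calls lost in it do not show an effect of neutrophil transcripts.

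**Figure D4:**
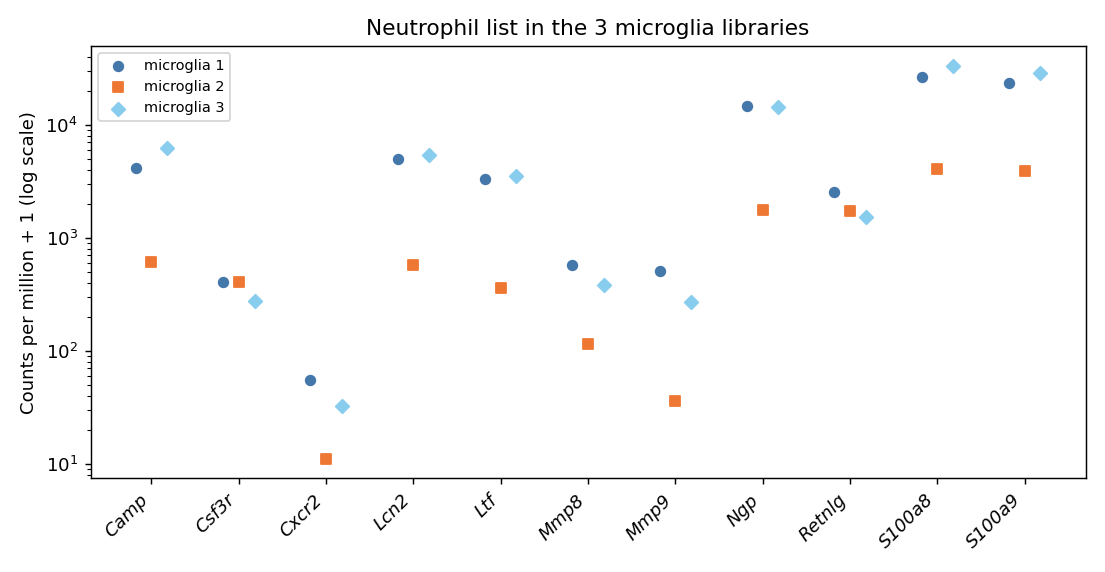
Levels of the 11 neutrophil list genes in the table in each microglia library, as CPM plus 1 on a log scale. Microglia 2 was the lowest in 9 of the 11 genes.

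Beside Icos, further lymphocyte receptor genes had no count in microglia. Nmur1 was at least 1264-fold higher in ILC2, Cd96 at least 621-fold and Il2rb at least 480.1-fold. Il2ra, the alpha chain of the interleukin-2 receptor, was at 553.2 and 190.2 CPM in ILC2 1 and ILC2 2. Fhl2, a regulator of transcription, was at least 633-fold higher, Faah, an enzyme that breaks down endocannabinoids, at least 577-fold and Pcsk1, a protease that matures peptide hormones, at least 560.4-fold. Among the genes without a count in ILC2, Cd86, a co-stimulatory ligand, was at least 2000-fold lower than in microglia. Cd300a, an inhibitory receptor, was at least 1285-fold lower and Mertk, a receptor for the uptake of dying cells, at least 1214-fold. Neutrophil genes were among the largest differences too: Wfdc21 was at least 2968-fold lower, Cd177 at least 1941-fold and Mmp8 at least 1483-fold. Ltf, encoding lactoferrin, had 1 count in ILC2, a ratio of 59400 (95% counting interval 10660 to 2346000), and Camp, encoding cathelicidin, had 3, a ratio of 30670 (10490 to 148700). Without microglia 1 and microglia 3 the adjusted p was 0.0595 for Pcsk1, 0.0876 for Wfdc21, 0.0671 for Ltf and 0.0797 for Camp. Without ILC2 1 it was 0.0716 for Ltf and 0.0926 for Camp, without ILC2 2 0.0882 and 0.104, and with limma-voom 0.0911 for Wfdc21, 0.191 for Ltf and 0.213 for Camp. With quantile normalization and limma-voom it was 0.135, 0.175 and 0.179 for these 3 genes. For Cd177 it was 0.0660 with quantile normalization and limma-voom. Across these 5 genes the lowest adjusted p of any setting ran from 8.82e-09 for Cd177 to 1.41e-05 for Wfdc21.

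ILC2 genes were higher in ILC2 than in microglia. Of 24 ILC2 identity genes, 14 were higher and 2 lower (18 and 3 when adjusted over the list alone; adjusted p = 1.11e-25). Gata3 was at 877.6 ± 326 CPM in ILC2 with 9 counts in microglia, and Bcl11b, a transcription factor of T cells and ILC2, was at least 238-fold higher. Il7r, the interleukin-7 receptor, had a log2 fold change of 5.16 ± 0.37 and Il1rl1 of 5.26 ± 0.76. Without microglia 1 and microglia 3, the adjusted p of Il1rl1 was 0.0779, the highest of its settings (lowest 1.26e-12). Of 21 type 2 cytokine and mediator genes, 8 were higher (12 over the list alone; adjusted p = 7.82e-07). Csf2, the growth factor GM-CSF, was at 155.7 ± 4.96 CPM in ILC2 and 1.71 ± 2.97 in microglia, and Areg at 216.0 ± 40.2 and 4.48 ± 3.92 CPM. Csf2 and Areg lost their call without ILC2 2 (adjusted p = 0.130 and 0.121, their highest, from lows of 1.41e-05 and 7.76e-06), without ILC2 1 (0.102 and 0.0668), without microglia 1 (both 0.0566) and without microglia 3 (0.0622 and 0.0726). Il13 was at 24.3 ± 4.33 CPM in ILC2 with 5 counts in microglia and did not pass (adjusted p = 0.0765, 0.0496 without microglia 3, and 0.00227 to 0.229 over the other settings). Of 18 neuropeptide and lipid mediator receptors, 7 were higher and 2 lower (adjusted p = 0.000148, and adjusted p = 0.0874 with an estimated correlation). Vipr2, a receptor of vasoactive intestinal peptide, was at 202.8 ± 59.8 CPM in ILC2 with 6 counts in microglia (adjusted p = 0.112 without microglia 1 and microglia 3, its highest, from 6.01e-06).

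Some lists of lymphocyte genes beyond those of ILC2 were higher in ILC2 than in microglia as well. The lists share genes: Il2ra is in the regulatory T cell and ILC2 identity lists, and Ctla4 in the regulatory T cell and residency lists. Of 20 genes of the T cell receptor complex and its signalling, 10 were higher (14 when adjusted over the list alone; adjusted p = 3.33e-15). Skap1, an adaptor of integrin activation, was at 717.4 ± 181 CPM in ILC2 and 3.07 ± 2.98 in microglia. Cd3e was at 12.4 ± 14.1 and 0.607 ± 1.05 CPM and did not pass (adjusted p = 0.0530, 0.0136 without microglia 1 and 0.0418 without ILC2 2, and 0.00657 to 0.433 over the other settings). Of 15 genes of tissue residency and inhibitory receptors, 7 were higher and 2 lower (adjusted p = 2.14e-05). Cxcr6, a chemokine receptor of resident lymphocytes, had a log2 fold change of 7.62 ± 0.47, and Ctla4, an inhibitory receptor, was at 18.82 and 113.6 CPM in ILC2 1 and ILC2 2 with no count in microglia. Of 10 regulatory T cell genes, 5 were higher (adjusted p = 1.26e-06), among them Il2ra, Ctla4 and Tnfrsf9, a co-stimulatory receptor that was at least 72.4-fold higher. Other lymphocyte lists did not pass: naive and central memory T cells (2 higher and 3 lower; adjusted p = 0.955), cytotoxic and effector genes (2 and 2; 0.343), natural killer cells and ILC1 (0 and 1; 0.520), ILC3 and type 17 (1 and 0; 0.649), cytokine receptors (5 and 4; 0.671), and chemokine receptors and adhesion (6 and 6; 0.323).

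All 20 microglia identity genes were lower in ILC2 than in microglia (adjusted p = 3.96e-40, and adjusted p = 0.0233 with an estimated correlation). Tmem119 had a log2 fold change of -7.55 ± 1.08, P2ry13 of -6.92 ± 0.87, P2ry12, a receptor that guides microglial processes to ATP, of -6.55 ± 0.77, and Csf1r, the survival receptor of macrophages, of -5.65 ± 0.88. Of 24 genes of disease-associated microglia, 14 were lower (17 over the list alone; adjusted p = 4.58e-20, and adjusted p = 0.0592 with an estimated correlation). Trem2, a lipid receptor of microglia, had a log2 fold change of -5.11 ± 0.44 and Apoe, a lipid carrier, of -3.81 ± 0.65. Of 18 complement and phagocytosis genes, 13 were lower (17 over the list alone; adjusted p = 1.82e-29). C1qa, a chain of complement C1q, had a log2 fold change of -5.50 ± 0.60 and Fcgr1, an antibody receptor, of -6.13 ± 0.42, and Cd14, the co-receptor for bacterial lipopolysaccharide, was at 9.32 ± 6.22 CPM in ILC2 and 955.5 ± 145 in microglia. Of 13 receptor and chemokine genes of aged and activated microglia, 5 were lower (8 over the list alone; adjusted p = 2.56e-08). Microglial transcripts were present in both ILC2 libraries: the median identity gene was at 1.58% and 1.195% of its level in microglia 2.

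Lysosomal, innate sensing and antigen presentation genes were lower in ILC2 than in microglia. Of 19 lysosome genes, 17 were lower (adjusted p = 1.38e-31), among them Lgmn, a lysosomal protease, with a log2 fold change of -4.77 ± 0.44, and Cd68, a lysosomal protein of macrophages, at 55.1 ± 41.6 CPM in ILC2 and 2189 ± 443 in microglia. Of 18 innate sensing genes, 5 were lower (10 over the list alone; adjusted p = 2.67e-09). Tlr7, a sensor of single-stranded RNA, was at 0.646 ± 0.914 CPM in ILC2 and 297.1 ± 28.3 in microglia, and the chemokine gene Ccl3 at 49.7 ± 27.9 and 1594 ± 181 CPM. Of 12 MHC class II presentation genes, 4 were lower (9 over the list alone; adjusted p = 6.89e-08, and adjusted p = 0.0909 with an estimated correlation). Ctss, the protease that trims the invariant chain, had a log2 fold change of -4.87 ± 0.40 and H2-DMa, a peptide-loading chaperone, of -2.87 ± 0.37. Cd74, the invariant chain itself, was at 363.7 ± 128 CPM in ILC2 and 1381 ± 463 in microglia and did not pass (adjusted p = 0.0623, and 0.00151 to 0.305 over the other settings).

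Genes of other cell types also differed between ILC2 and microglia. Of 11 neutrophil genes, 9 were lower in ILC2 (adjusted p = 5.06e-11, and adjusted p = 0.0773 with an estimated correlation). S100a8 was at 5.31 ± 7.51 CPM in ILC2 and 21300 ± 15320 in microglia, and its adjusted p ran from 1.82e-05 to 0.542 over the settings (0.0425 in the main test). It lost its call without any 1 of the ILC2 or microglia libraries (0.0571 to 0.151), without microglia 1 and microglia 3 (0.164), without the abundance trend (0.0558), with limma-voom (0.357) and with quantile normalization and limma-voom (0.542). Mbp, a myelin protein of oligodendrocytes, was at 356.4 ± 99.8 CPM in ILC2 and 58.0 ± 0.553 in microglia, and also at 267.9 ± 51.3 in T cells. Mbp was the 1 called gene of 10 on its list (adjusted p = 0.00226 for the list, and adjusted p = 0.0956 with an estimated correlation). Its call alone therefore does not show RNA of oligodendrocytes in ILC2. Of 12 endothelial and mural genes, 4 were lower (adjusted p = 0.00160, and adjusted p = 0.154 with an estimated correlation). Of 19 interferon response genes, 4 were lower (adjusted p = 0.000443, and adjusted p = 0.0955 with an estimated correlation). Of 17 immediate early genes, 1 was higher and 3 were lower (adjusted p = 0.0186, and adjusted p = 0.469 with an estimated correlation), and of 21 cell cycle genes, 1 was higher (adjusted p = 0.0247, and adjusted p = 0.475 with an estimated correlation). The 16 lists that did not pass had an adjusted p of 0.109 to 0.993. With an estimated correlation, 10 of the 19 list calls held, at an adjusted p of only 0.0140 to 0.0281.

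The comparison of T cells with microglia asked how brain T cells differ from the resident macrophages. Il2rb, the beta chain of the interleukin-2 receptor, was at 1182 ± 72.1 CPM in T cells and had no count in microglia, at least 3885-fold higher. Cd8a was at least 3037-fold higher and Cd4 at least 687-fold. Tmem119 was at 55.84 ± 44.97 CPM in T cells and 3645 ± 569 in microglia, a log2 fold change of -6.03 ± 0.84. The adjusted p was 2.60e-05 for Il2rb, 0.00253 for Cd8a, 0.000433 for Cd4 and 0.00135 for Tmem119. In build mm10, Il2rb lies on chromosome 15 from 78479256 to 78511621, Cd4 on chromosome 6 from 124864693 to 124888247 and Tmem119 on chromosome 5 from 113793729 to 113800396.

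In this comparison edgeR called 768 genes higher and 927 lower in T cells, with 3662 at an unadjusted p under 0.05. The libraries did not overlap in 37.2% of genes, where chance gives 10%. The 768 higher genes became 472 without T cells 2, and the 927 lower genes became 613 without microglia 1 and 591 without microglia 2. Fewer genes were called in both directions without microglia 1 and microglia 3, which had the most neutrophil transcripts. That fit leaves 1 microglia library, so the drop does not show an effect of these transcripts.

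Among the largest differences, Cd247, the zeta chain of the T cell receptor complex, was at least 1520-fold higher in T cells, Cd6 at least 1396-fold, Cd28, the main co-stimulatory receptor, at least 1380-fold, Gzmk at least 2340-fold, Cd96 at least 875-fold and Sh2d1a at least 854-fold. Among genes with no count in T cells, Cd177, a surface protein of neutrophils, was at least 1682-fold lower than in microglia, Tlr13, a sensor of bacterial RNA, at least 948-fold and Sort1, a sorting receptor, at least 380.4-fold. Sult1a1, a sulfotransferase, was at least 733.5-fold lower, Ptpro, a phosphatase, at least 535.5-fold and Trem3 at least 381-fold. Without microglia 1 and microglia 3 these 3 lost their call, with an adjusted p of 0.0674 for Sult1a1, 0.0575 for Ptpro and 0.160 for Trem3. Lcn2, encoding the iron-binding protein lipocalin 2, had 4 counts in T cells and was at 3637 ± 2664 CPM in microglia (adjusted p = 0.111 with limma-voom and 0.112 with quantile normalization, from 1.34e-24).

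All 20 genes of the T cell receptor complex and its signalling were higher in T cells than in microglia (adjusted p = 8.44e-43, and adjusted p = 0.0111 with an estimated correlation). Cd3e was at 1824 ± 403 CPM in T cells and 0.607 ± 1.05 in microglia, where microglia 1 held all 18 counts. Of 12 naive and central memory genes, 6 were higher (8 over the list alone; adjusted p = 2.07e-06), among them Tcf7, a transcription factor of memory T cells, at least 600.4-fold, Il7r with a log2 fold change of 4.45 ± 0.35 and Lef1, a partner of Tcf7, with 3.52 ± 0.47. Of 20 cytotoxic and effector genes, 15 were higher and 2 lower (17 and 2 over the list alone; adjusted p = 1.69e-16). Fasl was at least 568-fold higher, and Cxcr3, a chemokine receptor of type 1 lymphocytes, was at 802.3 ± 160.0 CPM in T cells and 2.82 ± 4.88 in microglia. Ifng was at 305.1 ± 145 and 2.06 ± 3.56 CPM (adjusted p = 0.0286), and Gzmb, a granzyme, at 327.3 ± 233 and 7.88 ± 7.96 CPM (adjusted p = 0.0330). The call of Ifng was lost without T cells 1 (adjusted p = 0.0718), T cells 2 (0.0561), microglia 2 (0.0651) or microglia 3 (0.0685) and with DESeq2 (0.0526), within a range from 1.30e-06. That of Gzmb was lost without T cells 1 (0.0559), T cells 2 (0.0948), microglia 2 (0.0540) or microglia 3 (0.103) and without microglia 1 and microglia 3 (0.149), within a range from 4.34e-05. Ptprc, the leukocyte antigen CD45, had a log2 fold change of 1.46 ± 0.31 (adjusted p = 0.0131; 0.0552 without T cells 2 and 0.219 without microglia 1 and microglia 3, within a range from 0.000259).

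Some other lymphocyte lists were also higher in T cells than in microglia. Of 15 tissue residency and inhibitory receptor genes, 6 were higher and 3 lower (adjusted p = 0.000312). Tigit, an inhibitory receptor, was at least 423-fold higher, and Cxcr6 had a log2 fold change of 6.41 ± 0.44. Of 10 regulatory T cell genes, 5 were higher (adjusted p = 1.47e-08), among them Tnfrsf4, a co-stimulatory receptor, at least 249-fold (adjusted p = 0.0759 without microglia 1 and microglia 3, its highest, from 6.78e-12). Of 24 ILC2 identity genes, 12 were higher in T cells and 3 lower (adjusted p = 2.45e-11), among them Gata3, at 160.5 ± 57.2 CPM with 9 counts in microglia, and Icos, at least 478.5-fold higher. Il5 was at 20.83, 9.58 and 5.478 CPM in T cells 1, 2 and 3 with 1 count in microglia, a ratio of 354 (95% counting interval 63.6 to 13990). Of 10 natural killer cell and ILC1 genes, 5 were higher and 1 lower (adjusted p = 0.00596, and adjusted p = 0.261 with an estimated correlation), among them Klre1, at 100.9 ± 51.2 CPM with no count in microglia. Of 8 ILC3 and type 17 genes, 4 were higher and 1 lower (adjusted p = 0.00770, and adjusted p = 0.259 with an estimated correlation). Among these, Cd163l1, a scavenger receptor of gamma delta T cells, was at least 117-fold higher. Of 19 chemokine receptor and adhesion genes, 9 were higher and 2 lower (adjusted p = 0.000791). The lists of type 2 cytokines and mediators (4 higher and 1 lower; adjusted p = 0.240) and of cytokine receptors (5 and 6; 0.0931) did not pass.

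All 20 microglia identity genes were lower in T cells than in microglia (adjusted p = 3.61e-41, and adjusted p = 0.0172 with an estimated correlation). Slc2a5, a fructose transporter of microglia, had a log2 fold change of -7.33 ± 0.54, P2ry12 of -5.68 ± 0.62, Csf1r of -5.53 ± 0.73 and Cx3cr1 of -5.38 ± 0.36. Of 24 genes of disease-associated microglia, 15 were lower (18 over the list alone; adjusted p = 3.73e-20, and adjusted p = 0.0592 with an estimated correlation). Trem2 had a log2 fold change of -5.44 ± 0.38, and Spp1, the phosphoprotein osteopontin, was at 46.1 ± 31.2 CPM in T cells and 1194 ± 548 in microglia. Of 18 complement and phagocytosis genes, 16 were lower (adjusted p = 1.35e-31). C3ar1, the receptor of complement C3a, had a log2 fold change of -7.10 ± 1.12 and Cd14 of -6.28 ± 0.50. Of 13 receptor and chemokine genes of aged and activated microglia, 8 were lower (10 over the list alone; adjusted p = 1.04e-06). Microglial transcripts were present in the T cell libraries: the median identity gene was at 0.535% to 2.46% of its level in microglia 2.

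Lysosomal, innate sensing and antigen presentation genes were lower in T cells than in microglia. Of 19 lysosome genes, 18 were lower (adjusted p = 8.06e-35), among them Lgmn with a log2 fold change of -5.48 ± 0.38. Of 18 innate sensing genes, 12 were lower (13 over the list alone; adjusted p = 4.00e-10), among them Nlrp3, an inflammasome sensor, at least 106-fold. Of 12 MHC class II presentation genes, 9 were lower (adjusted p = 7.87e-10, and adjusted p = 0.0487 with an estimated correlation). Ctss had a log2 fold change of -4.32 ± 0.32, and H2-Ab1, a class II chain, was at 68.4 ± 68.3 CPM in T cells and 682.5 ± 255 in microglia (adjusted p = 0.0766 without microglia 1 and microglia 3, its highest, from 1.88e-07). The log2 fold change of H2-Ab1 was -3.32 ± 0.66, and -4.64 without T cells 2.

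Neutrophil genes were higher in the microglia libraries than in T cells, with 10 of 11 called (adjusted p = 4.30e-12, and adjusted p = 0.0780 with an estimated correlation). S100a9, the partner of S100a8, was at 14.0 ± 14.6 CPM in T cells and at 23278, 3924 and 28771 CPM in microglia 1, 2 and 3 (adjusted p = 0.118 with quantile normalization and limma-voom, its highest, and 0.0583 with limma-voom, from 3.52e-27). Of 12 endothelial and mural genes, 4 were lower in T cells (adjusted p = 0.00165, and adjusted p = 0.209 with an estimated correlation). The 19 interferon response genes did not pass as a list (adjusted p = 0.0697), and the called members went both ways. Ifi27l2a had a log2 fold change of 2.21 ± 0.28, while Ifitm3, a block to viral entry, had -2.12 ± 0.34 (adjusted p = 0.101 without microglia 1 and microglia 3, its highest, from 7.11e-08). Of 21 cell cycle genes, 2 were higher (adjusted p = 0.174 for the list), among them Mcm2, a helicase subunit of DNA replication, with a log2 fold change of 3.25 ± 0.68 (adjusted p = 0.0776 without microglia 1 and microglia 3, its highest, from 5.88e-05). Cysltr1 was at 0.432 ± 0.748 CPM in T cells and 130.8 ± 34.0 in microglia, and Prss34 had no count in T cells and was at 99.98, 25.79 and 16.89 CPM in microglia 1, 2 and 3. The 17 lists that did not pass, interferon response and cell cycle among them, had an adjusted p of 0.0697 to 0.908, and 13 of the 18 list calls held with an estimated correlation.

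Lists of further cell types and of metabolism did not pass in any of the 3 comparisons. In the order ILC2 with T cells, ILC2 with microglia and T cells with microglia, the adjusted p was 0.372, 0.955 and 0.562 for B cells and plasma cells, and 0.649, 0.109 and 0.126 for border macrophages and monocytes. It was 0.852, 0.671 and 0.673 for dendritic cells, 0.955, 0.695 and 0.757 for neurons, and 0.126, 0.993 and 0.444 for astrocytes. For choroid plexus and ependymal genes it was 0.695, 0.955 and 0.908, for glycolysis 0.852, 0.784 and 0.649, and for fatty acid and cholesterol metabolism 0.455, 0.852 and 0.540. In no called list did the median or mean fold change point against the test; among the uncalled lists this was so for 9, 6 and 3.

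Genes highest in a population passed both of its comparisons. In ILC2 there were 21 such genes, among them Nmur1, Il1rl1, Il5, Ccr8, Klrg1 and Ramp1, with Rnf128, a ubiquitin ligase of anergic T cells, Slc6a13, a GABA transporter, Prnp, encoding the prion protein, and Tspan13. The smaller of the log2 fold changes was 5.81 for Nmur1, 4.19 for Rnf128, 3.95 for Slc6a13, 3.56 for Prnp and 2.97 for Tspan13. Against T cells, without ILC2 2, the adjusted p was 0.0564 for Rnf128, 0.120 for Slc6a13 and 0.0579 for Prnp, from lows of 1.17e-11, 1.37e-07 and 1.47e-09 over the settings. Slc6a13 also lost its call without ILC2 1 (0.0510), T cells 1 (0.0703) or T cells 2 (0.0530). In T cells there were 28, among them Cd6, Sh2d1a, Samd3, Klrc1, Klre1, Eomes, Izumo1r, Wdr95, Fasl and Cd4. The call against ILC2 was lost for Izumo1r without ILC2 2 (0.0576), T cells 1 (0.0703) or T cells 2 (0.0530), and for Wdr95 without any 1 of the ILC2 or T cell libraries (0.109 to 0.173) or without the abundance trend (0.0548), from lows of 1.81e-10 and 1.89e-07. In microglia there were 459, among them the neutrophil genes Cd177, Trem3, Itgb2l, Fpr1 and Fpr2 as well as Nav3, Mir99ahg, Eva1a, Lacc1 and Olfml2b. The calls of both comparisons would share 2.80, 3.78 and 44.1 genes if they fell independently. Because both use the same libraries, simulated data without an effect were tested too. There edgeR gave a mean of 0, 0 and 0.1 genes, with 43.4, 39.9 and 33.1 at an unadjusted p under 0.05 in both. With no effect the adjustment leaves few calls in either comparison. These values therefore do not show how many genes the shared libraries add where the populations differ. The 21 became 11 without ILC2 1 and 6 without ILC2 2, the 28 became 16 without T cells 1 and 15 without T cells 2, and the 459 became 301 without microglia 2 and 187 without microglia 1 and microglia 3.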

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

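The newer quasi-likelihood method, limma-voom, quantile normalization with limma-voom, and the fit without microglia 1 and microglia 3 were chosen after the data were seen; the other settings were planned. Over all settings run, no gene called in the main test was called in the opposite direction, and none of the 155 named results changed direction. Among these, all but 12 were called in the main test, 97 kept their call in every setting at the thresholds of the main test, and all 12 that were not called passed the thresholds in at least 1 setting. These 97 also kept it in the fits without libraries of the population that is not compared. In such fits no named call against microglia was lost. Between ILC2 and T cells, leaving out microglia libraries kept 98, 101 and 98 of the 120 calls (without microglia 1, 2 and 3) and 88 (without microglia 1 and microglia 3). Depdc7 lost its call in each of these 4 fits, Pdgfb without microglia 3 and without microglia 1 and microglia 3, Arhgef10l without microglia 3, and Nuak2 without microglia 1 and microglia 3. DESeq2 kept 120 of the 120 calls between ILC2 and T cells, 1254 of 1268 between ILC2 and microglia and 1666 of 1695 between T cells and microglia, and limma-voom kept 92, 1208 and 1623. The counts stayed within 1.5 times with prior counts of 0.1 and 5, a filter at a mean count of 50, the size factors of DESeq2 in edgeR, and the adjusted p alone. Quantile normalization moved the median log2 fold change by 0.123 between ILC2 and microglia and by 0.131 between T cells and microglia against limma-voom, and fold changes under it are relative to that shift. The number of lists called changed by over 1.5 times in 1 case: with an estimated correlation, 10 lists were called between ILC2 and microglia. The cause of the changes below was not tested, except that a setting with fewer libraries has fewer values to test.

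Between ILC2 and T cells, the genes higher and lower were 117 and 118 without a filter, 239 and 290 with DESeq2, 165 and 156 with the newer method, 169 and 123 with limma-voom, and 179 and 135 with quantile normalization and limma-voom. Fitted to only the 2 groups, 109 were lower, and without the abundance trend 35 were higher. Between ILC2 and microglia they were 1010 and 1241 with the newer method, 1024 and 1061 with limma-voom, 1102 and 1052 with quantile normalization and limma-voom, and 307 and 242 without microglia 1 and microglia 3, and DESeq2 called 1380 lower. Between T cells and microglia, 1620 were lower with DESeq2, 1581 with the newer method and 1470 with limma-voom, and 1155 were higher with quantile normalization and limma-voom. A log2 threshold of 2 left 475 higher, and without microglia 1 and microglia 3 there were 368 higher and 319 lower. The genes highest in ILC2 and in T cells were 41 and 59 without a filter and 39 and 72 with only the 2 groups, and 13 were highest in ILC2 without the abundance trend. Highest in ILC2, T cells and microglia were 66, 90 and 937 with DESeq2, 98, 105 and 1016 with the newer method, 122, 98 and 899 with limma-voom, and 130, 107 and 886 with quantile normalization and limma-voom. Without microglia 1 and microglia 3, 187 were highest in microglia, and that fit kept 468 of the 1268 and 605 of the 1695 calls against microglia.

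With 1 library of the 2 populations compared left out at a time, ILC2 had 18 to 47 genes higher and 35 to 44 lower than T cells, and 342 to 557 higher and 369 to 438 lower than microglia. T cells had 472 to 616 higher and 591 to 775 lower than microglia. With only libraries of the named population left out in turn, the genes highest in ILC2, T cells and microglia ran from 6 to 11, 15 to 21 and 301 to 340. Of the 120 calls between ILC2 and T cells, 43 were kept without ILC2 2, where 18 were called higher and 6 genes were highest in ILC2, and 52 without ILC2 1, where 32 were called higher. A group left with 1 library is assumed to vary like the others. No paired analysis was possible because the table's columns carry no replicate numbers, although the sample titles do, so the planned block for the replicate was not run, and quantile normalization, which needs log2 values, was run only with limma-voom. At this depth and spread, edgeR called 0% of the genes simulated with a 2-fold change, where a call also needs an estimate of at least that size. It called 3.08% to 4.69% of those with a 4-fold and 11.1% to 21.2% of those with an 8-fold change, so that many changes of these sizes may have been missed. Only 63 to 66 genes were changed at each size. The adjusted p depends on how many genes differ, so these shares may not hold where more genes do, as against microglia.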

Other observations

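The tests of neutrophil and microglial transcripts and the splits of the libraries were all chosen after the results were seen. Basophil and mast cell genes were measured in both ILC2 libraries. Prss34 was at 167.3 CPM in ILC2 1 and 608.5 in ILC2 2, Mcpt8 at 84.9 and 345.8, Cpa3, a carboxypeptidase of mast cells and basophils, at 22.1 and 116.7, and Fcer1a, a chain of the IgE receptor, at 118.2 and 140.5. In the 3 T cell libraries Prss34 had no count, and Fcer1a was at 3.32 ± 5.75 CPM. In microglia Prss34 was at 47.6 ± 45.6 CPM. Prg2, an eosinophil granule protein, was not tied to 1 population: it ran from 0 in microglia 3 to 3110 CPM in T cells 3.

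Transcripts of brain and blood cells outside the sorted populations were also present. Ttr, the thyroid hormone carrier made by the choroid plexus, was at 1867 ± 860 CPM in microglia, 1595 ± 978 in T cells and 1836 ± 1827 in ILC2, from 492.9 CPM in T cells 2 to 3128 in ILC2 2. Alas2, an enzyme of haem synthesis in red cell precursors and the most abundant erythroid gene in the table, was at 85.0 ± 58.9, 54.1 ± 20.7 and 58.1 ± 48.8 CPM in microglia, T cells and ILC2. The heat shock gene Hspa1a, which sorting and tissue dissociation can induce, was at 1405 ± 222 CPM in T cells, 719.5 ± 38.2 in microglia and 519.4 ± 349 in ILC2.

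Neutrophil transcripts differed between the microglia libraries. S100a8, Ngp, Chil3 and Anxa1 were at 7.35, 8.19, 7.39 and 5.11 times the microglia 2 level in the mean of microglia 1 and microglia 3, and Lyz2, which microglia also express, at 1.68 times. Scaling or library size of microglia 2 as the whole cause is argued against, since 1 of 20 microglia identity genes was lowest in that library. A second list of genes of neutrophils and their precursors, of which Lyz2, Cybb, Ly6c2, Cxcr4 and Anxa1 are also expressed by other leukocytes, had 27 of 33 genes lowest in microglia 2, against 26.3% of all tested genes, so that cells or RNA of neutrophils and their precursors may have contributed to the microglia libraries in unequal amounts. Retnlg and Csf3r, of the first list, were not lowest there; a sort on surface markers would remove neutrophils only if it used a marker that excludes them, which the labels do not say, and no biological explanation was tested.

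Microglial transcripts were present in every T cell and ILC2 library. Of 20 microglia identity genes, 18 were lowest in T cells 1 among the T cell libraries. In a second list without identity genes, the disease-associated microglia and complement genes called lower in T cells, 25 of 31 were lowest in that library, against 31.9% of all tested genes and 11 of 20 T cell receptor genes, so that cells or RNA carried over from microglia may account for part of them. Not every microglial gene followed. Mertk, an identity gene at 377.4 CPM in microglia 2, and Cd86, at 667.8, had no count in ILC2. Tlr13, at 382.4 CPM in microglia 2, had no count in T cells. These genes were among the largest differences, but carry-over at 1 even share would have brought counts of them. Shares were taken against microglia 2, in which most neutrophil genes were lowest. Reads exchanged with the microglia libraries would therefore bring neutrophil genes in at least the same share as identity genes. In T cells 1, T cells 2 and ILC2 1 the median neutrophil gene was at 0%, 0.0626% and 0.189% of that level. The median identity gene was at 0.535%, 2.46% and 1.58%, which argues against exchange as the whole cause in these 3 libraries. In T cells 3 and ILC2 2 the neutrophil share was 0.832 and 1.04 times the identity share, so by these medians exchange cannot be told apart from carry-over there. The median hides uneven genes. In ILC2 2, S100a8 was at 10.6 CPM against 4072 in microglia 2, and Camp at 0.238 against 608.9. Lcn2 went the other way, at 7.14 CPM against 572.3. The 3 libraries under 0.2 times were short of the 4 set as the bound. The labels give no other group to compare, so no biological explanation was tested.

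The 3 T cell and 3 microglia libraries can be split in 10 ways into groups of 3, too few for a share under 0.05. The real split gave 1695 genes and the highest other split 0 with edgeR, and 1 of the 10 splits, the real one, gave as many. For gene lists the real split gave 18 and the highest other 17, again with 1 of 10 as many, and with an estimated correlation 13 and 1. The other splits called 10 to 17 lists at the preset correlation. Each of them sets 2 libraries of 1 population and 1 of the other against the reverse, so part of the difference between the populations remains in it, and its calls do not show how many lists pass without a difference. The mixing also puts the difference between the populations into the spread within each group. The 0 genes of the other splits therefore do not show how many genes pass without a difference either.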
